A study of Arabidopsis thaliana with 24 samples.

How the data were processed

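The samples were total RNA from the third true leaf of Arabidopsis thaliana Col-0 wild-type seedlings, dissected while the leaf was still made of dividing cells and measured about 0.1 mm2. Per the labels' protocols, seedlings grew on nylon mesh over 0.5 MS medium at 22 °C with 16 h of light and 8 h of dark, and 9 days after stratification the mesh was moved to fresh control medium or to medium with 25 mM mannitol, a poorly metabolised sugar alcohol used as a mild osmotic stress. Leaves were taken 1.5, 3, 12 and 24 h after the transfer, the last of these when the plants were 10 days old. The 8 groups of treatment and time held 3 arrays each, 24 in all. Per the design text, the replicates came from 3 independent biological experiments and each sample pooled many plants. No 2 arrays of a group held identical values.

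RNA was labelled with biotin and hybridised to Affymetrix ATH1 arrays. Per the submitters' processing notes, the authors processed the arrays with RMA, which corrects background, quantile normalizes the arrays against each other and summarises the probes of a gene into 1 value. The deposited values are on a log2 scale, with column medians between 6.44 and 6.54 and no value below 2.58. The RMA version, the assignment of probes to genes and the choice of genes were not given in the sources used here. The table held 20777 Arabidopsis locus identifiers, each once, where the analysis had been laid out for Affymetrix probe sets, so every count below is of loci and no choice between probe sets of a gene was needed. Of these, 20508 occur in the TAIR10.1 annotation, which was used for gene symbols only, and 269 kept their identifier alone. Quantile normalization gives the arrays nearly the same distribution, so a change of most genes in 1 direction would be hidden. Background correction and the scanner compress the changes of dim genes, so log2 changes of genes near the floor are likely to be understated. The number of arrays limits the precision.

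The log2 values were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 8 groups and 1 spread per locus shared by all 24 arrays (16 residual degrees of freedom, prior degrees of freedom 5.08 after empirical Bayes moderation). Mannitol was compared with control at each time, where the 4 comparisons share no arrays. The mean of the 4 mannitol effects, the mean effect at 12 and 24 h minus that at 1.5 and 3 h, an F-test of any change of the effect between times, and the control leaves at 3, 12 and 24 h against 1.5 h came from the same fit. A locus was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, with no filter on dim loci or on the size of the change. Errors beside log2 changes are the moderated standard errors (SE), and each group mean rests on n = 3 arrays. A comparison of 3 arrays with 3 in a permutation test could not go below p = 0.1, so single genes were judged by limma's adjusted p, which borrows the spread of all loci.

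The comparisons, 33 gene lists, the genes named in the text and the alternatives were fixed before the data were examined. The lists held 469 entries for hormone, stress, cell cycle, cell wall, growth, photosynthesis and cell-type marker genes, of which 427 were measured and 42 were not analysed here for want of a value. Each list was tested at each time with limma's camera, which asks whether its members moved in 1 direction relative to all other loci, with an inter-gene correlation preset at 0.01, and again with the correlation estimated from the data, adjusted over the 132 tests of 33 lists at 4 times. The named genes were the 10 largest rises and 10 largest falls among called loci whose 3 mannitol arrays all lay on the same side of the 3 control arrays, up to 4 members of each list with the smallest p, and 16 genes always named for their part in ethylene, gibberellin, cell cycle and stress responses. For the tests of change with time they were the 8 loci with the smallest p, for the mean effect 10, and for control leaves the 6 largest rises and falls at 24 h and 5 clock genes. A further list test of the control leaves over time was chosen later.

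Replicate numbers were shared by all groups. Their pairing was checked by the correlation across loci of the deviations of same-numbered control and mannitol arrays from their group means. At 12 h these were 0.217, 0.261 and 0.124, above 0.1 in every pair, so the numbers were taken to pair the arrays at that time. At the other times at least 1 pair lay below 0.1. Over all times a control array matched the mannitol array of its own number best in 10 of 12 pairs, so pairing there is not excluded. The main fit left the pairing out at every time, and fits with the replicate number as a block were run as alternatives.

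The fit was tested on simulated data in which 200 loci per comparison were changed by known amounts among the 20777. For a log2 change of 0.5 it recovered 68.7% of the changed loci at 1.5 h and 74.6% at 3, 12 and 24 h. For a log2 change of 1 it recovered 97% at 1.5, 12 and 24 h and 98.5% at 3 h. The share of false calls was 6.84% at 1.5 h, 2.67% at 3 h, 5.73% at 12 h and 6.25% at 24 h. The simulated noise was independent between loci and arrays. It left out the shared deviations of same-numbered arrays and the unequal quality of arrays, so these rates may not hold for the real data. Alternatives covered each time fitted alone, replicate blocks, a trended and robust prior, median centring and quantile normalization of the arrays, a filter on the dimmest 33.3% of loci, array weights, an equal-variance 2-sample test, a 2-fold filter, and leaving out each array or replicate number. An alternative on several probe sets per gene was not run because each locus had 1 value.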

Results

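Transcript levels were measured on 24 arrays in the growing leaf (the third true leaf) of Arabidopsis seedlings moved to 25 mM mannitol or to control medium, with 3 biological replicates per treatment at 1.5, 3, 12 and 24 h. All values are RMA values on the log2 scale for 20777 loci. Within groups the lowest correlation between replicate arrays, across loci, lay between 0.991 and 0.996, and the median replicate SD between 0.0926 and 0.139, highest in the control leaves at 3 h. The first 3 principal components held 33.8, 23.7 and 10.2% of the variance. Control and mannitol leaves of each time were compared to ask how soon, and in which genes, the stress altered a leaf whose cells were still dividing.

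**Figure D1:**
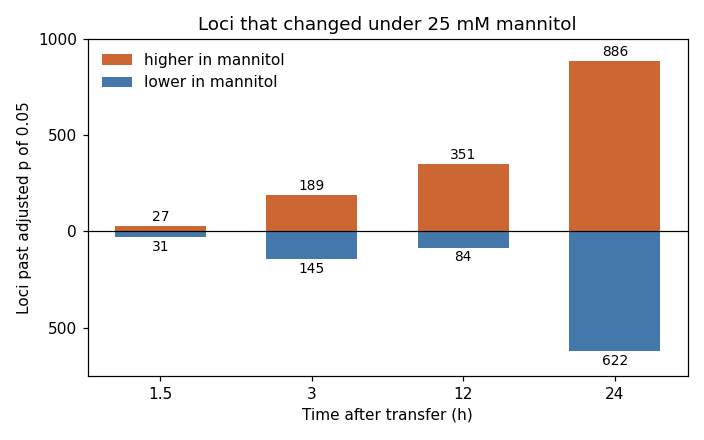
Loci called higher (bars up) and lower (bars down) in mannitol than in control leaves at 1.5, 3, 12 and 24 h after transfer, at a limma adjusted p under 0.05 with 3 arrays per group. The count rose from 58 at 1.5 h to 1508 at 24 h.

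After 1.5 h in mannitol, the gene AT1G55450 rose 5.57-fold (log2 change 2.48 ± 0.30 SE, adjusted p = 0.000404), AT5G28630 rose 3.31-fold and AT1G05575 by 1.81 ± 0.24 on the log2 scale. ARGOS (AT3G59900), which promotes the growth of lateral organs and lowers the response to ethylene, rose 2.98-fold, from 5.84 ± 0.30 to 7.41 ± 0.20 (SD, n = 3). The largest rise was 11.5-fold in TCH3 (AT2G41100), a touch-induced calmodulin-like protein (log2 change 3.52 ± 0.65). Falls were smaller: XTH15 and XTH16, xyloglucan-modifying enzymes of the cell wall, changed by -0.99 ± 0.17 and -0.65 ± 0.12, the arabinogalactan protein gene AGP21 by -0.73 ± 0.11 and ALG10 by -0.60 ± 0.09. AT1G05575 and AT1G19020 lay among the dimmest 33.3% of loci in control leaves, so their changes may be understated, which was not tested. The other named rises, AT2G24600, AT2G46600, AT1G19020, EDA39 and AT4G36500, lay between 1.61 and 1.84, and the other named falls, AT3G19680, LGT8, AGP7, AT1G75140, AT5G62130 and AT1G23205, between -0.57 and -0.77. In limma 58 loci were called, 27 higher and 31 lower (42 and 18 with the time fitted alone, 43 and 34 with the replicate number as a block, 58 and 69 or 127 in all with array weights), and 21 of the rises but 0 of the falls reached 2-fold, while 1288 loci had an unadjusted p under 0.05. All 3 mannitol arrays lay on 1 side of all 3 control arrays at 2810 loci, 13.5% against the 10% that chance gives. The count was 28, 34 and 21 without control replicates 1, 2 and 3, and 25 and 24 without mannitol replicates 1 and 3. Of the 20 named genes, 12 lost their call without some single array; for TCH3 the adjusted p was 0.0637 and 0.126 without control replicates 1 and 3 and 0.128 without mannitol replicate 3, and the highest p of XTH15 and XTH16 were 0.0697 and 0.09, without control replicates 1 and 3.

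Of the 33 gene lists, 8 were called by camera at 1.5 h, 6 higher and 2 lower, and 2 of these held with an estimated correlation. With the preset correlation, other splits of the 6 arrays gave up to 11 lists at 1.5 h. At 3, 12 and 24 h they gave up to 8, 10 and 19. The number of lists called so is thus weak evidence of a mannitol effect, above all at 1.5 and 24 h. Those splits held part of the mannitol effect themselves, so their counts do not show what chance alone would give. Ethylene perception and signalling was higher, with 3 of 14 measured members called and 6 adjusted over the list alone: ARGOS, its homologue ARL (1.44 ± 0.21) and EBF2 (0.66 ± 0.14), an F-box protein that removes the ethylene transcription factor EIN3. The list's adjusted p was 4.69e-09, and 0.04 with an estimated correlation. Xyloglucan endotransglucosylases were lower, with 2 of 13 members called and 3 adjusted over the list alone. Camera gave adjusted p = 6.76e-05, and adjusted p = 0.04 with an estimated correlation. The stress-responsive ERF factors were higher as a list, although 0 of 17 members was called in limma, 12 had an unadjusted p under 0.05 and 10 passed adjusted over the list alone. This list had an adjusted p of 8.29e-11, and of 0.0771 with an estimated correlation. Among the stress-responsive WRKY factors 0 of 15 was called, 6 had an unadjusted p under 0.05 and 5 passed adjusted over the list alone. For the list as a whole the adjusted p was 4.24e-08, and 0.167 with an estimated correlation. WRKY33, at 2.06 ± 0.45, had an adjusted p of 0.0584, and ERF6, at 1.54 ± 0.41, one of 0.181. Smaller shifts were called for ZAT and AZF zinc finger genes, 0 of 8 members (2 at an unadjusted p under 0.05, 0 adjusted over the list alone), pathogen defence, 1 of 14 (CYP81F2, 1.18 ± 0.24; 2 adjusted over the list alone), sugar starvation, 0 of 12 (3 at an unadjusted p under 0.05, 2 adjusted over the list alone) and, downward, aquaporins, 0 of 13 (0 at an unadjusted p under 0.05). Their adjusted p were 0.0058, 0.0462, 0.018 and 0.0166, and with an estimated correlation adjusted p = 0.256, 0.419, 0.481 and 0.574. Outside these lists MPK3, a stress-activated MAP kinase, rose by 1.21 ± 0.23 and GAI, a DELLA repressor of gibberellin responses, fell by 0.44 ± 0.09 on the log2 scale. EBF2, CYP81F2 and GAI lost the call without any 1 of the arrays other than mannitol replicate 2, with highest p of 0.305, 0.291 and 0.225, and MPK3 without control replicate 1 or 3 or mannitol replicate 3, with a highest p of 0.157.

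By 3 h AT3G16530, which encodes a lectin-like protein, rose 15.2-fold (log2 change 3.93 ± 0.34 SE, adjusted p = 4.4e-07), and PLA2A (AT2G26560), a lipid acyl hydrolase, 9.54-fold (3.25 ± 0.23). PNP-A, a natriuretic peptide thought to act on water and ion balance, rose 6.98-fold (2.80 ± 0.53) and AT1G55450 5.97-fold. The organic cation transporter gene OCT3 fell by 1.44 ± 0.18 on the log2 scale, XTH6 by 1.25 ± 0.19, XTH7 by 1.06 ± 0.20 and the potassium channel gene KT2/3 by 1.08 ± 0.25. PLA2A, PNP-A, AT1G72060, AT2G39400 and AT5G52750 lay among the dimmest 33.3% of loci in control leaves, so their changes may be understated. The other named rises, TCH3, AT1G72060, AT2G39400, AT5G48540, AT5G28630 and AT5G52750, lay between 2.50 and 3.24, and the other falls, AT1G29660, AT3G20370, MSRB6, AT5G63180, AT1G60590 and AT5G17700, between -1.01 and -1.16. In limma 334 loci were called, 189 higher and 145 lower, with 79 and 10 of them at least 2-fold. The count was 157 with the time fitted alone, 206 with array weights and 530 with a replicate block within each time (257 higher and 273 lower), and without control replicate 2 the split was 200 and 206. At 2842 loci (13.7%, against 10% by chance) the groups did not overlap. Among the 20 named genes 3 lost the call without single arrays: TCH3 without control replicate 3 (adjusted p = 0.0552), AT1G60590 without control replicate 2 or mannitol replicates 1 and 2 (highest p 0.0999) and KT2/3 without any 1 of the 6 arrays (highest p 0.113).

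At 3 h camera called 11 lists, 6 higher and 5 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.0803. Among the stress-responsive WRKY factors 2 of 15 rose and 4 passed adjusted over the list alone: WRKY30 by 2.34 ± 0.27 and WRKY6 by 0.90 ± 0.17. As a group they had an adjusted p of 3.64e-06, and of 0.256 with an estimated correlation. Pathogen defence was higher with 2 of 14 members up and 1 down, the same numbers adjusted over the list alone: CYP81F2 and MYB51, an enzyme and a regulator of indole glucosinolates, rose by 1.84 ± 0.24 and 0.94 ± 0.19, while the defensin gene PDF1.2b fell by 0.74 ± 0.16. By camera the adjusted p was 0.00106, and with an estimated correlation the adjusted p was 0.167. Aquaporins, the water channels, fell in 4 of 13 measured members, 8 adjusted over the list alone, PIP2;1 by 0.47 ± 0.09 among them. The list's adjusted p was 1.37e-07, and 0.12 with an estimated correlation. Markers of the stomatal lineage fell in 2 of 10, TMM by 0.37 ± 0.09 and EPF1 by 0.40 ± 0.10, with 3 adjusted over the list alone. Camera gave adjusted p = 0.00152, and adjusted p = 0.242 with an estimated correlation. Xyloglucan endotransglucosylases fell in 1 of 13, XTH24 by 0.47 ± 0.11, with 3 adjusted over the list alone. This list had an adjusted p of 0.00106, and of 0.0803 with an estimated correlation. DNA replication genes were lower as a list with 0 of 21 called, 9 at an unadjusted p under 0.05 and 2 adjusted over the list alone (adjusted p = 0.000143, and adjusted p = 0.378 with an estimated correlation), and auxin response genes with 0 of 16 called, 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone. For the list as a whole the adjusted p was 0.015, and 0.12 with an estimated correlation. The ethylene signalling list was higher with 1 of 14 called, the kinase gene CTR1 (0.52 ± 0.10), and 2 adjusted over the list alone. As a group they had an adjusted p of 0.00812, and of 0.342 with an estimated correlation. At this time ARGOS, ARL and EBF2 stood at -0.12, -0.00 and 0.01. Higher too were the ERF factors, 1 of 17 (RAP2.6L, 0.81 ± 0.14; 1 adjusted over the list alone), the MAPK module genes, 0 of 9 (1 at an unadjusted p under 0.05, 1 adjusted over the list alone), and the ZAT and AZF genes, 0 of 8 (3 at an unadjusted p under 0.05, 1 adjusted over the list alone). Their adjusted p were 0.0475, 0.0166 and 0.0393, and with an estimated correlation adjusted p = 0.668, 0.378 and 0.418. MYB51 lost its call without mannitol replicate 3 (adjusted p = 0.0535), PDF1.2b without control or mannitol replicate 3 (highest p 0.105) and PIP2;1 without mannitol replicate 1 (adjusted p = 0.0506). The other 3 aquaporins that fell, PIP2;5, PIP2;6 and TIP1;1, lost theirs too, with highest p of 0.0641 without mannitol replicate 1, 0.0848 without mannitol replicate 2 and 0.191 without mannitol replicate 3, and control replicates 1 and 2 also ended calls among them. TMM, EPF1 and XTH24 lost theirs without any 1 of 4 or 5 arrays, every array of this time among them, with highest p of 0.138, 0.178 and 0.161, and EPF1 also with the replicate number as a block (adjusted p = 0.0554).

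At 12 h rises outnumbered falls by about 4 to 1. AT3G16530 rose 35.2-fold (log2 change 5.14 ± 0.34 SE, adjusted p = 3.36e-09), the blue copper protein gene BCB (AT5G20230) 13.8-fold, PLA2A 11.6-fold and the transcription factor gene WRKY30 (AT5G24110) 11.3-fold, from 3.55 ± 0.09 to 7.04 ± 0.14 (SD, n = 3). The chitinase-like genes AT2G43590 and AT2G43620 rose 13.1-fold and 10.9-fold. Falls reached 3.07-fold in JAL22, a jacalin-type lectin, 2.95-fold in XTH6 and 2.09-fold in ESP, which directs glucosinolate breakdown to nitriles. AT5G48540 rose 16-fold. In control leaves AT3G16530, AT5G48540, PLA2A, PNP-A, WRKY30 and AT1G19020 lay among the dimmest 33.3% of loci, as AT5G26280 did in mannitol leaves. Their folds may be understated. Without control replicate 1 PNP-A rose by 4.56 and TCH3 by 4.43, and TCH3 by 2.79 without control replicate 3. The other named rises, PNP-A, TCH3 and AT1G19020, lay between 3.32 and 3.52 on the log2 scale and the other falls, AT5G26280, OCT3, AT1G52100, AT1G31690, AT5G62210, AT3G20370 and AT3G50570, between -1.09 and -1.38. In limma 351 loci were higher and 84 lower, 435 in all, with 157 and 11 at least 2-fold, and 3532 loci (17%, against 10% by chance) had groups that did not overlap. The count was 265 and 270 without control replicates 2 and 3, and 261 without mannitol replicate 3. With array weights it was more than 1.5 times its value. Of the 20 named genes ESP alone lost its call, without control replicate 2 (adjusted p = 0.0732) or mannitol replicate 1 (adjusted p = 0.0605).

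At 12 h camera called 11 lists, 7 higher and 4 lower, and 3 of these with an estimated correlation. Pathogen defence rose in 6 of 14 members, the same number adjusted over the list alone: the camalexin enzyme genes CYP71A13 and PAD3 by 2.94 ± 0.23 and 1.55 ± 0.20, the antifungal protein genes PR5 and PR4 by 2.75 ± 0.26 and 1.91 ± 0.25, CYP81F2 by 1.86 ± 0.24 and MYB51 by 1.35 ± 0.19. By camera the adjusted p was 9.88e-11, and with an estimated correlation the adjusted p was 0.0182. The mitochondrial dysfunction list rose in 4 of 10 members and 8 adjusted over the list alone: UGT74E2 by 1.65 ± 0.33, the alternative NADH dehydrogenase gene NDA2 by 0.44 ± 0.08, the alternative oxidase gene AOX1A by 1.91 ± 0.42 and BCS1 by 0.91 ± 0.22. The list's adjusted p was 1.62e-08, and 0.0336 with an estimated correlation. Ethylene perception and signalling rose in 5 of 14 and 7 adjusted over the list alone, with ARL at 1.55 ± 0.21, ARGOS at 1.07 ± 0.17 and the receptor gene ERS1 at 0.62 ± 0.11. Camera gave adjusted p = 3.1e-10, and adjusted p = 0.0371 with an estimated correlation. WRKY factors rose in 5 of 15, led by WRKY30, WRKY33 (2.07 ± 0.45) and WRKY6 (1.42 ± 0.17), and 10 adjusted over the list alone. This list had an adjusted p of 5.75e-14, and of 0.0603 with an estimated correlation. ERF factors rose in 3 of 17, ERF5 by 1.64 ± 0.32, RAP2.6L by 0.92 ± 0.14 and ORA59 by 0.80 ± 0.16, and 7 adjusted over the list alone. For the list as a whole the adjusted p was 4.32e-09, and 0.103 with an estimated correlation. ZAT and AZF genes rose in 2 of 8, ZAT11 (0.90 ± 0.17) and ZAT6, and 4 adjusted over the list alone. As a group they had an adjusted p of 0.00026, and of 0.127 with an estimated correlation. The MAPK modules rose in 1 of 9, MPK3 (0.97 ± 0.23), which was also the member adjusted over the list alone. By camera the adjusted p was 0.000891, and with an estimated correlation the adjusted p was 0.204.

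Among the lists that were lower at 12 h, photosynthesis genes had a median change of -0.17, with 0 of 20 called, 10 at an unadjusted p under 0.05 and 2 adjusted over the list alone. The adjusted p of the list was 2.81e-07, and 0.378 with an estimated correlation. Stomatal lineage markers had 0 of 10 called, 5 at an unadjusted p under 0.05 and 3 adjusted over the list alone. Camera gave adjusted p = 6.27e-06, and adjusted p = 0.0921 with an estimated correlation. DNA replication genes had 0 of 21 called, 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone. This list had an adjusted p of 1.9e-05, and of 0.302 with an estimated correlation. Aquaporins fell in 1 of 13, PIP2;6 (-0.44 ± 0.11), and 3 adjusted over the list alone. For the list as a whole the adjusted p was 0.000399, and 0.335 with an estimated correlation. At 12 h AOX1A lost its call without control replicate 2 or mannitol replicate 3 (highest p 0.129, at a change of 1.26), WRKY33 without control replicates 2 or 3 or mannitol replicate 3 (highest p 0.0739) and ORA59 without mannitol replicate 3 (adjusted p = 0.0774). BCS1 (all arrays but mannitol replicate 2), ZAT6 (all but mannitol replicate 1), and MPK3 and PIP2;6 (control replicates 2 and 3, mannitol replicates 1 and 3) lost theirs too, with highest p of 0.204, 0.239, 0.151 and 0.182.

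At 24 h AT3G16530 rose 42.2-fold (log2 change 5.40 ± 0.34 SE, adjusted p = 2.54e-10), the berberine-bridge-like enzyme genes AT1G26380 and AT1G26420 rose 31.9-fold and 18.1-fold, and WRKY30 rose 29.4-fold, from 3.75 ± 0.21 to 8.63 ± 0.35 (SD, n = 3). PNP-A rose 20-fold, the peroxidase gene Prx37 (AT4G08770) by 4.17 ± 0.20 and the thaumatin-like gene PR5 by 3.94 ± 0.26. The largest falls were AT5G62210 (-1.82 ± 0.19), the gibberellin-regulated peptide gene GASA1 (-1.74 ± 0.35), ESP (-1.70 ± 0.22) and OCT3 (-1.48 ± 0.18), and the anthocyanin genes DFR and GSTF12 fell by 1.47 ± 0.39 and 1.47 ± 0.35 on the log2 scale. AT1G26380, AT1G26420, WRKY30, PNP-A and PLA2A lay among the dimmest 33.3% of loci in control leaves, so their folds may be understated. The other named rises, AT2G43590, PLA2A and BCB, lay between 3.98 and 4.56, and the other falls, AGP24, MSRB6, KAT5 and XTH6, between -1.29 and -1.40. In limma 886 loci were higher and 622 lower, 1508 in all or 7.26% of loci, with 288 and 25 at least 2-fold. With each array centred on its median the split was 766 and 858, and with the 24 h arrays fitted alone 585 and 329, or 914 loci. Groups did not overlap at 4171 of 20777 loci, against the 10% that chance gives, and the count was 978 without mannitol replicate 3. DFR lost its call without control replicates 2 or 3 or mannitol replicates 1 or 3 (highest p 0.0948), GSTF12 without control replicate 3 or mannitol replicate 1 (highest p 0.0665) and AGP24 without control replicate 2 or mannitol replicates 1 or 3 (highest p 0.103, at a change of -0.71 without control replicate 2).

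At 24 h camera called 13 lists, and 5 of these with an estimated correlation. Other splits of the 6 arrays gave up to 19 lists with the preset correlation. Mitotic genes were lower as a list at 24 h: 17 of 22 fell and 19 adjusted over the list alone, with a median change of -0.41. As a group they had an adjusted p of 5.92e-17, and of 0.04 with an estimated correlation. The cyclin gene CYCB1;1 fell by 0.54 ± 0.10 on the log2 scale, the aurora kinase genes AUR1 and AUR2 by 0.50 ± 0.08 and 0.49 ± 0.09, and HIK, a kinesin of cytokinesis, by 0.51 ± 0.09. CDKB2;1 fell by 0.35 ± 0.09 and, outside the list, the D-type cyclin CYCD3;1 by 0.35 ± 0.10. DNA replication genes fell in 3 of 21, CDC45 by 0.52 ± 0.09 among them, and 7 adjusted over the list alone. By camera the adjusted p was 3.61e-07, and with an estimated correlation the adjusted p was 0.204. The list of CDK inhibitors and endoreduplication genes fell as well, in 3 of 16 members and 5 adjusted over the list alone: the APC activator gene CCS52B by 0.46 ± 0.08, WEE1 by 0.50 ± 0.11 and SMR1 by 0.65 ± 0.15. The adjusted p of the list was 0.00177, and 0.04 with an estimated correlation. Stomatal lineage markers fell in 5 of 10 and 7 adjusted over the list alone, with the polarity gene BASL at -0.74 ± 0.10, the peptide gene EPF2 at -0.60 ± 0.12 and TMM at -0.50 ± 0.09. Camera gave adjusted p = 3.61e-07, and adjusted p = 0.0603 with an estimated correlation. Aquaporins fell in 9 of 13 and 11 adjusted over the list alone, PIP1;5 by 0.55 ± 0.11 among them. This list had an adjusted p of 5.5e-07, and of 0.145 with an estimated correlation. Heat shock protein genes fell in 1 of 10, HSP17.6II by 0.76 ± 0.13, the member also called when adjusted over the list alone. For the list as a whole the adjusted p was 0.00825, and 0.288 with an estimated correlation. CDKB2;1 lost its call without control replicates 1 or 2 or mannitol replicate 3 (highest p 0.152), CYCD3;1 without control replicates 2 or 3 or mannitol replicate 1 (highest p 0.232), WEE1 without mannitol replicate 3 (adjusted p = 0.0618) and SMR1 without control replicate 2 (adjusted p = 0.0537).

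Of the lists that were higher at 24 h, ethylene perception and signalling rose in 11 of 14 members, the same number adjusted over the list alone. As a group they had an adjusted p of 4.56e-14, and of 0.0178 with an estimated correlation. These were the receptor genes ERS1, ERS2 and ETR2 (0.82 ± 0.11, 0.92 ± 0.21 and 0.67 ± 0.15), CTR1, EIN3, EIL1, EBF1, EBF2 (0.94 ± 0.14), RTE1, ARGOS (1.25 ± 0.17) and ARL (1.96 ± 0.21). Pathogen defence rose in 7 of 14, the same number adjusted over the list alone, with CYP71A13 at 3.67 ± 0.23, PAD3 at 2.77 ± 0.20 and MYB51 at 2.27 ± 0.19. By camera the adjusted p was 5.56e-13, and with an estimated correlation the adjusted p was 0.0178. The mitochondrial dysfunction list rose in 6 of 10 and 7 adjusted over the list alone, with UGT74E2 at 2.29 ± 0.33, BCS1 at 1.31 ± 0.22 and AOX1A at 1.61 ± 0.42. The adjusted p of the list was 4.48e-07, and 0.04 with an estimated correlation. WRKY factors rose in 10 of 15 and 12 adjusted over the list alone, WRKY33 by 2.16 ± 0.45 and WRKY53 by 1.70 ± 0.32 among them. Camera gave adjusted p = 6.89e-14, and adjusted p = 0.0603 with an estimated correlation. ERF factors rose in 8 of 17 and 9 adjusted over the list alone, ERF5 by 2.14 ± 0.32, RAP2.6L by 1.75 ± 0.14, ERF11 by 1.61 ± 0.27 and ERF98 by 1.41 ± 0.16 among them. This list had an adjusted p of 2.03e-10, and of 0.0803 with an estimated correlation. ZAT11 and ZAT6 rose by 1.90 ± 0.17 and 1.82 ± 0.29, 2 of 8 ZAT and AZF genes with 3 adjusted over the list alone. For the list as a whole the adjusted p was 8e-05, and 0.103 with an estimated correlation. MPK3 (1.17 ± 0.23) and MPK11 rose, 2 of 9 MAPK module genes and the same number adjusted over the list alone. As a group they had an adjusted p of 0.022, and of 0.404 with an estimated correlation. WRKY33 rose by 2.74 without control replicate 1 and 1.41 without control replicate 3. AOX1A lost its call without control replicates 2 or 3 or mannitol replicates 1 or 3 (highest p 0.117), and MPK11 without control replicates 2 or 3 or mannitol replicate 1 (highest p 0.107).

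**Figure D2:**
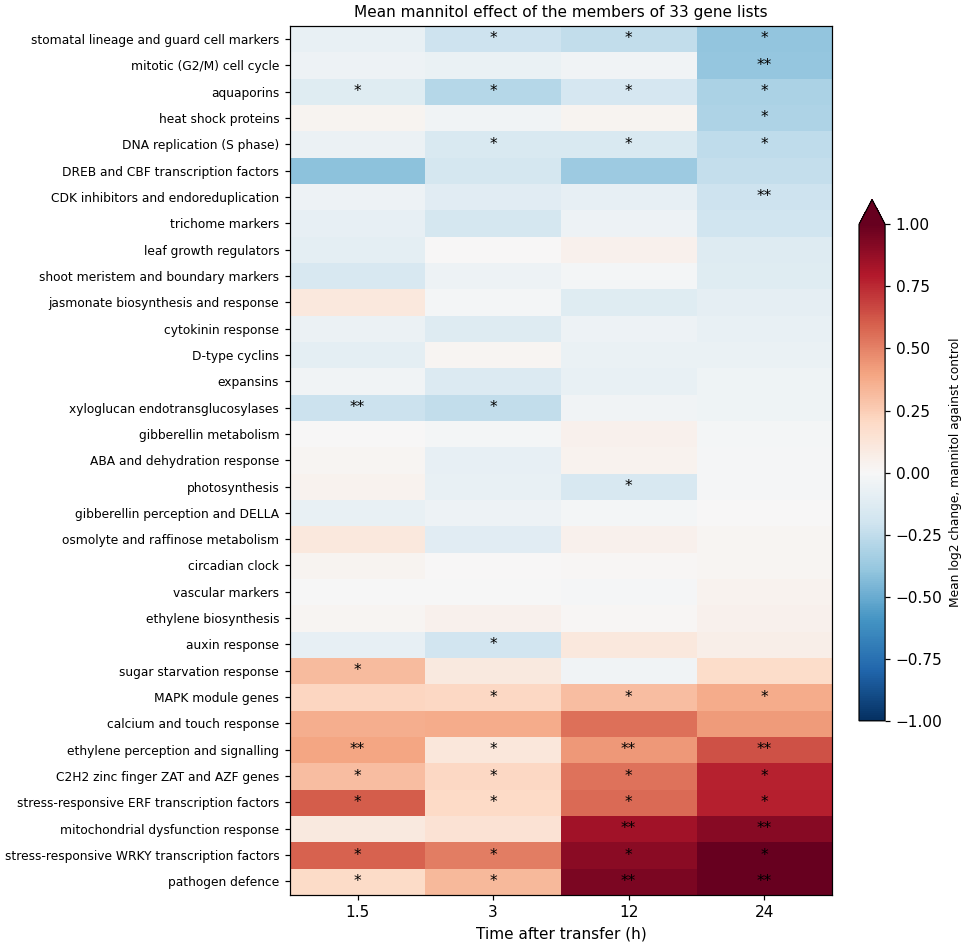
Mean log2 change, mannitol against control, of the measured members of 33 gene lists (vertical axis) at 1.5, 3, 12 and 24 h after transfer (horizontal axis), with colours capped at 1, one star for a camera adjusted p under 0.05 and a pair of stars where the call also held with an estimated correlation. Pathogen defence, the mitochondrial dysfunction list and ethylene signalling have a pair of stars at 12 and 24 h. Ethylene signalling and xyloglucan endotransglucosylases have a pair at 1.5 h. Mitotic genes and the list of CDK inhibitors and endoreduplication genes have a pair at 24 h. With the preset correlation, other splits of the arrays gave more lists than the real one at 1.5 and 24 h, though part of the mannitol effect stayed in those splits.

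At no time did camera call the remaining 16 lists. Their smallest adjusted p over the 4 times was 0.0628 for calcium and touch response, 0.0862 for expansins, 0.0976 for D-type cyclins and 0.0976 for DREB and CBF factors, 0.105 for cytokinin response, 0.11 for jasmonate, 0.127 for leaf growth regulators and 0.152 for gibberellin perception and DELLA genes. It was 0.163 for shoot meristem markers, 0.224 for osmolyte metabolism, 0.283 for trichome markers, 0.407 for ABA and dehydration response, 0.501 for ethylene biosynthesis, 0.667 for gibberellin metabolism, 0.833 for vascular markers and 0.843 for the circadian clock. Single members of such lists did change at 24 h: HAI1, a phosphatase of ABA signalling, fell by 0.65 ± 0.14, RD22 rose by 0.70 ± 0.13, and GA3OX1, which makes active gibberellin, fell by 0.65 ± 0.15, a call it lost without control replicate 2 (adjusted p = 0.0722). Of the genes always named, ERF6, ZAT10, ACS2, ACS6, GA2OX6, GA20OX1, RGL3, EXPA10 and RD29A passed in limma at none of the 4 times. Their changes at 24 h were 0.72, 1.21, -0.06, 0.15, 0.89, -0.14, 0.18, 0.31 and -0.17, with adjusted p of 0.451, 0.151, 0.921, 0.915, 0.159, 0.751, 0.548, 0.12 and 0.759. On the control arrays at 24 h GA20OX1 read 4.03 to 4.54 and RGL3 3.80 to 4.13. Both lay below 4.74, the bound of the dimmest 33.3% of loci in that group. Changes of GA20OX1 and RGL3 may thus be understated, and their lack of a call does not show that they were unresponsive.

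**Figure D3:**
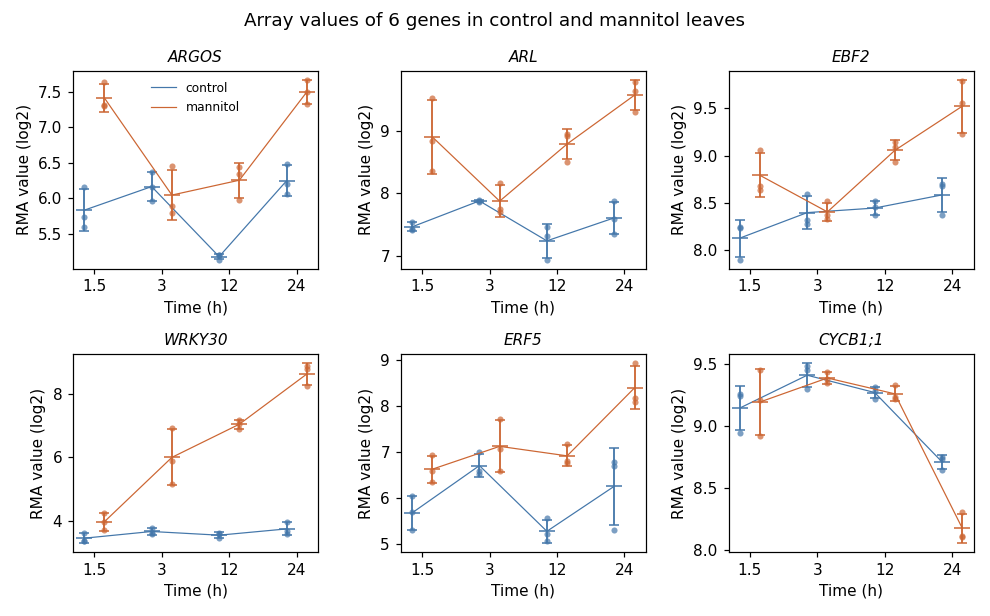
Log2 RMA values of 6 genes in control and mannitol leaves at 1.5, 3, 12 and 24 h after transfer (evenly spaced on the horizontal axis), with a point per array and the mean ± SD of n = 3. ARGOS and ARL were higher in mannitol leaves at 1.5, 12 and 24 h, WRKY30 rose from 3 h on, ERF5 was called at 12 and 24 h, and CYCB1;1 fell at 24 h.

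Of the 27 loci higher at 1.5 h, 19 were also higher at 3 h, 25 at 12 h and 23 at 24 h, and of the 31 lower at 1.5 h, 9 were also lower at 3 h, 4 at 12 h and 15 at 24 h. In limma 1666 loci were called at 1 or more of the 4 times, 937 higher and 729 lower, and 0 were called in opposite directions. At 1 time only 1197 were called, at 2 times 290, at 3 times 158 and at all 4 times 21, so 469 were shared by at least 2 times. Between 12 and 24 h, 322 higher loci were shared where 15 would be by chance, and 57 lower loci where 2.51 would be, and between 1.5 and 3 h the shared numbers were 19 and 9 where chance gives 0.246 and 0.216. The log2 changes of neighbouring times correlated across loci, which are not independent replicates, with Pearson r of 0.392 (1.5 and 3 h), 0.599 (3 and 12 h) and 0.802 (12 and 24 h) and Spearman rho of 0.159, 0.26 and 0.454. Averaged over the 4 times, 2097 loci were called, 1084 higher and 1013 lower (1001 and 1171 with each array centred on its median), of which 138 and 2 reached 2-fold. The smallest p belonged to PLA2A (mean log2 change 2.90 ± 0.11, adjusted p = 1.47e-13), AT1G26420 (2.19 ± 0.08) and the glutathione transferase gene GSTU12 (1.65 ± 0.06). After these came AT3G16530 (3.99 ± 0.17), AT1G26380 (2.76 ± 0.12), WRKY30 (2.81 ± 0.13), AT5G28630 (2.27 ± 0.11), AT1G65500 (1.97 ± 0.09), AT1G02360 (1.84 ± 0.08) and the sugar transporter gene STP4 (1.57 ± 0.07).

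The mannitol effect at 12 and 24 h exceeded that at 1.5 and 3 h by 2.97 ± 0.23 for CYP71A13, 2.27 ± 0.18 for CYP71A12 and 2.09 ± 0.15 for CYP79B2, which makes indole-3-acetaldoxime (adjusted p = 3.34e-08, 8.42e-08 and 1.01e-08). GSTU12 went from 0.06 at 1.5 h through 0.91 and 1.91 to 3.73 at 24 h, AT1G26420 from 0.05 through 1.36 and 3.16 to 4.18, Prx37 from 0.05 to 4.17, AT1G65500 from 0.10 to 3.84 and the lipase gene GLIP1 from -0.05 to 2.09. In limma 271 loci differed between late and early effects, 250 with a more positive and 21 with a more negative late effect. Any change of the effect between times was called for 240 loci by the F-test, 361 without mannitol replicate 2 at 24 h and 154 without mannitol replicate 3 at 24 h. Camera called 13 lists for late against early effects, and pathogen defence alone also with an estimated correlation (adjusted p = 0.00979).

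The control leaves alone changed with the time after transfer, which sets the background against which mannitol acted. The clock genes CCA1 (AT2G46830) and LHY (AT1G01060), transcribed in the morning, were 38.3-fold and 55.6-fold lower at 12 h than at 1.5 h (log2 change -5.26 ± 0.09 and -5.80 ± 0.14 SE, adjusted p = 1.64e-20 and 5.73e-18) and at 24 h 0.66 ± 0.09 and 0.72 ± 0.14 higher. CCA1 at 12 h lay among the dimmest 33.3% of loci, so its fold may be understated. TOC1, transcribed in the evening, rose by 1.87 ± 0.11 at 12 h, and its change of 0.13 ± 0.11 at 24 h was not called (adjusted p = 0.447). GI rose by 1.06 ± 0.11 at 3 h and fell by 0.58 ± 0.11 at 12 h and 0.42 ± 0.11 at 24 h, and PRR9 was not measured. In mannitol leaves these genes followed the same course, with CCA1 at 3.62 ± 0.10 at 12 h against 3.67 ± 0.22 in control leaves (SD, n = 3), and the clock list was not called at any time. At 24 h TCH3 was 6.96-fold higher than at 1.5 h, the phosphate starvation genes PAP17 and G3Pp1 were 5.32-fold and 5.25-fold higher, and the protease inhibitor gene UPI and the pathogenesis-related gene PRB1 were 4.11-fold and 3.51-fold lower. The other named rises, AT3G16670, AT5G48570 and AT5G19240, lay between 2.18 and 2.69 on the log2 scale and the other falls, AT5G59330, AT1G28710, AT4G22490 and AT5G38320, between -1.94 and -2.05. Without replicate 2 of 24 h AT5G59330 fell by 1.38 and AT4G22490 by 1.34. AT5G38320 lay among the dimmest 33.3% of loci at 24 h, so its fall may be understated.

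In limma 656 loci differed in control leaves between 3 and 1.5 h, 367 higher and 289 lower, 2698 between 12 and 1.5 h, 1420 higher and 1278 lower, and 3219 between 24 and 1.5 h, 1286 higher and 1933 lower. With each array centred on its median the split was 537 and 195 at 3 h and 1984 and 1052 at 24 h, so no direction is given for the 24 h count. At 3 h the count was 269, 428 and 279 without replicates 1, 2 and 3 of 1.5 h, and 399 and 1072 without replicates 1 and 2 of 3 h. At 24 h it was 2107 without replicate 1 of 1.5 h, and 2109 and 2029 without replicates 1 and 2 of 24 h. A TOC1 rise of 0.39 ± 0.11 at 3 h was lost without any 1 of 5 arrays, all but replicate 2 of 3 h (highest p 0.188), and the GI fall at 24 h without replicate 1 of 1.5 h or replicate 2 of 24 h (highest p 0.0893).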

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

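In this part the test of the 3 h effect of ARGOS, ARL and EBF2 against their other times, and those of their control level at 3 h, were chosen only after the result was seen. The results below stand out because the mannitol effect differed between times, by a test of that difference itself. The F-test called 240 loci and the comparison of late with early effects 271. With 100 relabellings of the arrays within each time, after the mean mannitol effect was removed, only the real labels (1 of 100) gave as many in either test, and the highest of the others were 12 and 4. Such counts were thus unlikely from chance labels, though 100 relabellings cannot show a share below 1 in 100. The relabelling ignored replicate numbers. Effects particular to a time stayed in the data and can lower the counts of the other labels.

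The adjusted p of the F-test was 4.26e-10 for GSTU12, 1.15e-09 for AT1G26420, 3.03e-08 for GLIP1, 3.73e-08 for Prx37, 4.66e-08 for AT1G65500, 9.69e-08 for AT1G26380 and 9.69e-08 for CYP79B2. It was 1.22e-07 for CYP71A12, 3.12e-07 for CYP71A13, 5.27e-07 for AT2G43590, 8.69e-07 for PR5, 8.94e-07 for PLA2A, 9.04e-07 for STP4 and 1.4e-06 for WRKY30. PAD3 had 2.66e-05, AT1G02360 4.35e-05, PR4 5.15e-05, BCB 6.78e-05 and AT3G16530 6.9e-05. ZAT11 had 0.00102, WRKY6 0.00172, RAP2.6L 0.00416, AT2G39400 0.00507, WRKY28 0.007, AT5G48540 0.0105, MYB51 0.0105 and AT1G72060 0.0109. ERF98 had 0.0115, CYP81F2 0.012, UGT74E2 0.0153, ORA59 0.0176, AT2G43620 0.0176 and the kinase gene CTR1 0.0452.

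Among genes that fell at 1 or more times, the adjusted p of the F-test was 0.00042 for AT1G52100, 0.00171 for AT5G63180, 0.00198 for JAL22, 0.00214 for AT5G62210, 0.00269 for AT1G29660, 0.00541 for AT3G20370 and 0.00628 for AT5G17700. It was 0.00658 for KAT5, 0.0199 for MSRB6, 0.0231 for AT1G75140, 0.038 for CCS52B, 0.0406 for ALG10 and 0.0408 for ESP. The organ growth genes ARGOS and ARL had 0.00128 and 0.00259.

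Whole lists also differed between late and early effects in camera, adjusted over 33 lists: pathogen defence with 2.88e-11, mitotic genes with 8.56e-07, WRKY factors with 8.56e-07, the mitochondrial dysfunction list with 1.32e-06 and ethylene signalling with 2.22e-06. The others were ERF factors (0.000295), stomatal lineage markers (0.000498), DNA replication (0.0148), auxin response (0.0169), ZAT and AZF genes (0.022), photosynthesis (0.0359), xyloglucan endotransglucosylases (0.0428) and jasmonate (0.0487). With an estimated correlation the adjusted p was 0.00979 for pathogen defence, 0.0519 for the mitochondrial list and above 0.1 for the rest.

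For the count at each time the arrays allow 10 splits, too few for a share under 0.05. The real counts at 1.5, 3, 12 and 24 h were 58, 334, 435 and 1508, and the highest of the other splits 0, 0, 1 and 35, so that 1 of 10 splits, the real one, reached each count. For control leaves at 3, 12 and 24 h the real counts were 656, 2698 and 3219 and the highest others 1, 0 and 10. For lists the real counts were 8, 11, 11 and 13 and the highest others 11, 8, 10 and 19, with 3, 1, 1 and 6 of 10 splits as high as the real one. Each other split had unequal numbers of mannitol arrays on its sides, so part of the mannitol effect stayed in it. At 1.5 and 24 h the list count with the preset correlation thus does not set mannitol apart from the other groupings. It cannot tell whether chance or the remaining mannitol effect gave the counts of those groupings. With an estimated correlation the real list counts were 2, 0, 3 and 5 and the highest others 1, 0, 0 and 2. For the mean effect 1 of 100 relabellings, the real one, gave 2097 loci and the highest other 116, so chance labels were unlikely to give such a count. Here too the relabelling ignored replicate numbers, and the mannitol effect itself stayed in the data.

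ARGOS, ARL and EBF2 were higher in mannitol leaves at 1.5, 12 and 24 h, with mean log2 effects of 1.23, 1.08 and 1.38, but not at 3 h (-0.04). However, EBF2 lost its 12 h call without control replicate 3 (adjusted p = 0.094), mannitol replicate 1 (0.0706) or mannitol replicate 3 (0.099). It lost its 1.5 h call without any 1 of the arrays of that time other than mannitol replicate 2. The 3 h effect lay below the mean of the other times by 1.42 ± 0.20 for ARGOS and 1.65 ± 0.25 for ARL (adjusted p = 0.00598 for both), 2 of 18 loci that passed, all lower, while EBF2 (0.73 ± 0.16, adjusted p = 0.101) did not, and the ethylene signalling list had an adjusted p of 0.000134, and of 0.253 with an estimated correlation. A single array was argued against, since without any 1 of the 6 arrays the mean effect at 3 h was at most 0.0292. A higher level in the control leaves at 3 h was argued against as the whole cause, since it made up 26.8% of the mean shortfall against 1.5 h, 47% against 12 h and 0.0282% against 24 h. For ARGOS alone it made up 19.6% against 1.5 h, 82.5% against 12 h and -5.99% against 24 h, so against 12 h it stays open. The mannitol effect of ARGOS and ARL did differ between times in the F-test (adjusted p = 0.00128 and 0.00259). For EBF2 such a difference stays open. What made the effect differ was not tested.

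At 12 h 351 loci rose and 84 fell. Differences of scale left after RMA were argued against: with arrays centred on their medians or quantile normalized, at least 75.2% of called loci rose. RMA had already quantile normalized the values, so a shift that it removed or made cannot be tested this way. The signal floor stays open, since it may hide falls: of the called loci with a control level above the median of all loci 61.6% rose (109 of 177), and of the dimmer ones 93.8% (242 of 258).

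Mitotic genes were lower at 24 h by a mean of 0.39 on the log2 scale. A single array was argued against, since without any 1 of the 6 arrays the mean stayed at -0.348 or lower. Differences of scale left after RMA were argued against, with a mean of -0.395 or lower after median centring or quantile normalization. A shift that RMA itself removed or made cannot be tested this way. A more advanced leaf stage in mannitol samples stays open. Over 20755 other loci the mannitol effect followed the change of control leaves from 1.5 to 24 h. The slope was 0.288 (0.175 to 0.429) after correction for the shared control arrays, or 0.115 without it. The mitotic genes, which fell by 0.29 in control leaves, would need 1.34 (1.2 to 1.55). That change of control leaves also holds the hour of day and the time since transfer. The slope of 0.288 was low enough to argue against leaf stage by the rule set in advance. It does not measure leaf stage alone, however, and thus cannot decide. The mitotic genes were lower in mannitol than in control leaves at 24 h. That mannitol lowered them other than through leaf stage stays a hypothesis.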

How the results depend on the processing

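The comparisons in this part were all set out in advance. No gene list called in the main fit, and none of the 703 results for named genes, of which 234 had been called, passed with the opposite sign under any alternative run. The F-test results among the 703 have no sign. Lists called only under an alternative were not checked for sign. Which direction held more called loci did change in several counts. With arrays centred on their medians the higher and lower loci were 29 and 25 at 1.5 h, 766 and 858 at 24 h, 1001 and 1171 for the mean effect and 1984 and 1052 for control leaves at 24 h. With the block within each time they were 257 and 273 at 3 h, and without control replicate 3 of 1.5 h 1026 and 1030 for control leaves at 12 h. At 12 h, for late against early effects and for control leaves at 3 h, more loci were higher under every alternative run. The additive replicate block, the trended and robust prior, median centring, quantile normalization and the filter on the dimmest 33.3% of loci left every total within 1.5 times its value, though not every count of higher or lower loci. Of the 234 named calls the block ended 1, the prior 11, centring 0 and quantile normalization 3. The filter removed 22 of them untested and ended 0 of the other 212.

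Fitting each time alone gave 157 loci at 3 h and 914 at 24 h and ended 52 of 185 named calls. The replicate block within each time gave 530 at 3 h and ended 3 named calls, of AT4G36500 at 1.5 h, EPF1 at 3 h and EXPA5 at 24 h. Array weights gave 127, 206 and 663 at 1.5, 3 and 12 h, with the lowest weight, 0.335, on control replicate 3 at 3 h, and ended 11 of 234 named calls. The equal-variance 2-sample test at each time alone gave 0, 0, 3 and 20 loci in time order, with 1502, 1601, 2084 and 2660 at an unadjusted p under 0.05, and ended 176 of 185 named calls. For these alternatives the cause was not tested, except that a time fitted alone rests on 6 arrays. A 2-fold change besides the adjusted p gave by construction smaller counts: 21, 89, 168 and 313 in time order, 140 for the mean effect, 102 for late against early effects and 30, 328 and 196 for control leaves at 3, 12 and 24 h. It ended 82 of 226 named calls and cannot be applied to the F-test.

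Of the 8, 11, 11 and 13 lists called in time order, 2, 0, 3 and 5 held with an estimated correlation. The rotation test fry called 3 at 1.5 h and 5 at 3 h, and a background without the dimmest loci 5 and 7, where the cause was not tested. The 469 loci shared by at least 2 times became 274 at an adjusted p of 0.01, a stricter threshold by construction.

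Leaving out 1 array, or 1 replicate number from all groups, gave 1 to 53 loci at 1.5 h, 129 to 406 at 3 h, 212 to 450 at 12 h and 646 to 1652 at 24 h. The ranges were 1055 to 2264 for the mean effect, 72 to 385 for late against early effects, 56 to 361 for the F-test and 74 to 1072, 1292 to 2221 and 938 to 3077 for control leaves at 3, 12 and 24 h. The counts of called lists were refitted without replicate numbers only, not single arrays, and ranged over 8 to 9, 10 to 11, 11 to 13 and 12 to 14. The mitotic list alone was also refitted without each array of 24 h, with a highest camera adjusted p of 7.44e-14. Fewer arrays leave fewer residual degrees of freedom. Single arrays ended 66 named calls and replicate numbers 110.

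Replicate numbers paired the arrays by the rule only at 12 h. The own number was the best match in 10 of 12 pairs, so pairing at the other times is not excluded. Same-numbered control and mannitol arrays deviated alike at r above 0.1 across loci in 8 of 12 pairs over all times. With the additive block the counts were 77, 399, 509 and 1638 in time order.

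The alternative of 1 probe set per gene was run as loci with 1 gene in the reference and ended 0 named calls, and the mean of all probe sets was not run because each locus had 1 value. How far signal over background limits falls of dim loci was not settled.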

Other observations

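The list tests of the control leaves in this part were chosen only after the counts for control leaves had been seen, and no explanation of them was tested. At 12 h against 1.5 h, photosynthesis genes fell in 17 of 20 members and 19 adjusted over the list alone, with a median change of -0.58 (camera adjusted p = 3.12e-24 over 99 tests). DNA replication genes fell in 15 of 21 and 17 adjusted over the list alone (adjusted p = 5.2e-12), and aquaporins in 8 of 13 and 12 adjusted over the list alone (adjusted p = 3.16e-09). With an estimated correlation the adjusted p of each was 0.13.

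At 24 h against 1.5 h, when the plants were a day older, mitotic genes fell in 10 of 22 members and 15 adjusted over the list alone (adjusted p = 6.9e-07, and adjusted p = 0.242 with an estimated correlation), and leaf growth regulators in 8 of 18 and 9 adjusted over the list alone (adjusted p = 2.84e-05, and adjusted p = 0.172 with an estimated correlation). Trichome markers fell in 4 of 5 and 5 adjusted over the list alone (adjusted p = 0.000653, and adjusted p = 0.204 with an estimated correlation). Photosynthesis genes rose in 10 of 20, the same number adjusted over the list alone, with a median change of 0.21 (adjusted p = 1.29e-07, and adjusted p = 0.369 with an estimated correlation). Heat shock protein genes rose in 6 of 10 and 7 adjusted over the list alone, with a median change of 1.11 (adjusted p = 1.01e-07, and adjusted p = 0.13 with an estimated correlation). Vascular markers rose in 3 of 8 and 4 adjusted over the list alone (adjusted p = 0.00123, and adjusted p = 0.13 with an estimated correlation).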
